A study of Mus musculus with 6 samples.

How the data were processed

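RNA was measured in single cells of mouse intestinal organoids (C57BL/6, wild type, age 8 weeks) on a droplet platform. Per the labels, cells were released by mechanical disruption and digestion, sorted to discard debris and dead cells, and made into 3-prime libraries, for which a version 2 reagent guide is named. bcl2fastq 2.17, Cell Ranger 3.1.0 and the GRCm38 build are named in the submitters' processing notes, with no role or order given. The values analysed are counts of UMIs per gene and cell, as deposited by the authors, with no normalization. Each file held 55335 genes. Raw reads were not used here.

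The labels gave the groups: day-4 vehicle, RXR antagonist (5 µM), all-trans retinoic acid (10 µM) and vitamin A-free medium, with 1 library each, and day-1 vehicle with 2 libraries. The unit of the doses is written "μm" there. No paired analysis was possible because groups share no more than 1 replicate number. The choices below and the gene lists, cell markers, comparisons and alternatives were fixed before the data were examined, except where stated.

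Cells were to be kept with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs. The filter removed 0 barcodes, because the deposited barcodes had at least 1001 genes and at most 9.996% mitochondrial UMIs, so they had been filtered already. Scrublet, as implemented in scanpy, marked from 0 to 1.11% of barcodes per library at its own threshold, which did not work as a filter. The planned rule was applied instead: the highest-scoring barcodes were removed at 0.8% per 1000 barcodes, which took 102 to 249 barcodes per library (2.86% to 4.47%). Depth after filtering ranged from 47258161 to 62567817 UMIs per library. A gene with 0 UMIs in a library could then lie at up to 3 UMIs, and such a gene is given a bound against that floor. Genes with 1 to 3 UMIs are given a ratio with its counting interval.

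UMIs of all kept cells were summed per library and scaled to the total (CPM). Log2 ratios used a pseudocount of 5 CPM, and genes needed 10 CPM in at least 1 of the 2 libraries. Folds of named genes are ratios of CPM without pseudocount. The comparisons were the antagonist, retinoic acid and vitamin A-free medium against the day-4 vehicle, the antagonist against retinoic acid, and day 4 against day 1. With 1 library per treatment no test was made. Genes at least 2-fold apart were counted as a description by size.

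The 34 gene lists were retinoic acid response, retinoid metabolism and receptors, crypt stem cell, Wnt target, enterocyte, villus tip enterocyte, intestinal transcription factors, goblet, Paneth, enteroendocrine, tuft and M cell. Further lists were regenerative and fetal-like epithelium, YAP and TEAD target, PPAR target and fatty acid oxidation, LXR target, FXR target and bile acid transport, VDR, PXR and CAR target, cholesterol biosynthesis, DNA replication, mitosis and Notch. The last were interferon, antigen presentation, antimicrobial and secreted host defence, p53, NRF2, unfolded protein response, glycolysis and hypoxia, dissociation and immediate early, immune, fibroblast and smooth muscle, endothelial and red blood cell. Some genes are on more than 1 list, such as Isx on the retinoic acid and transcription factor lists. Cyr61 and Ctgf are older names of Ccn1 and Ccn2. A list was described by the median log2 ratio of members at the floor, by members at least 1.5-fold apart, by an interval from 2000 bootstrap draws over members, and by its place among 10000 random lists matched in 20 expression bins. Genes of a list are not independent replicates. UMIs of close paralogs, such as the Defa, Reg3, Ly6, Cyp3a, Ces and Sprr2a families, may be assigned uncertainly between members.

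Named genes were, for each comparison, the 12 highest and 12 lowest log2 ratios without predicted genes, up to 4 members of each list with the largest ratios, 6 retinoid receptor genes, and 12 marker genes whose UMI shares were measured at equal depth. For day 4 against day 1 the direction had to hold against each day-1 library. Some genes that this rule names are not reported here.

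Over 8028 genes, the chi-square per degree of freedom between the day-1 libraries was 115, against a highest value of 3.85 in 100 random splits of the pooled cells, and they shared 9 barcodes, against 2 to 17 for other pairs. So they are not the same cells or random parts of 1 library, but these values do not tell separate cultures from separate loadings of 1 culture. By the planned rule, which used these checks, they were counted as 2 libraries, and the labels also list them as separate samples. UMI sums were then tested with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, quasi-likelihood F-test, Benjamini-Hochberg adjustment at 0.05). DESeq2 1.42.0 was the alternative. Tested on simulated data with 200 changed genes in each of 5 simulations, edgeR recovered 82.4% of genes changed 2-fold and 100% of those changed 4-fold, with 42.8 false calls per simulation. False calls were thus a larger share of all calls than the 0.05 that the adjustment aims at. These simulations changed fewer genes than edgeR called in the data, so they do not give the share of false calls there. In a simulated pair of libraries, 100% of 200 genes changed 2.83-fold passed the 2-fold limit and 0 unchanged genes did. This pair held counting error only, with no variation between libraries, so it does not tell how often an unaffected gene passes. Between the 2 real day-1 libraries, 65 genes passed. The ratio intervals held the simulated ratio in 95.5% of cases.

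Cells of the 6 libraries were clustered together in scanpy 1.11.5 (anndata 0.12.19, scaling to 10000 UMIs per cell, logarithm, 2000 variable genes, 30 components rounded to 4 decimals, 15 neighbours, Leiden resolution 1 with leidenalg 0.10.2 and igraph 0.11.9, seed 0). Neighbour distances and weights were rounded too, because a first clustering proved to depend on the last digits of the arithmetic, and all cluster values come from a repeat with rounding, made after the data were seen. No batch integration was made, since library and treatment are the same. A cluster was named when at least 3 markers of a class were at 10 CPM and 1.5-fold above the other cells, a threshold set after the data were seen. Goblet and Paneth clusters formed 1 class. Comparisons within a class needed 200 cells in both libraries. For shares of cells with a UMI, each cell was thinned to 3000 UMIs, and 149, 88, 127, 44, 252 and 264 shallower cells were left out (day-4 vehicle, antagonist, retinoic acid, vitamin A-free medium and day-1 libraries 1 and 2).

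Alternatives were all deposited barcodes, a stricter cell filter (1500 genes, 3000 UMIs, 10% mitochondrial), doublets kept, TMM factors, DESeq2 size factors, equal weight for each cell, thinned cells, pseudocounts of 1 and 10 CPM, no floor, a floor of 50 CPM, and each day-1 library left out. For edgeR they were DESeq2, RLE factors and no count filter. For clusters they were resolutions of 0.5 and 2, another random seed, and each library alone. For UMI shares they were 1500 UMIs and no thinning. For counts of list members they were ratios relative to the median of all genes, chosen after the data were seen. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9. Gene positions came from GENCODE M21.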

Results

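Single-cell RNA counts were collected from mouse intestinal organoids, which are cultures of gut epithelium that grow from single cells and form stem, absorptive and secretory cells. The 6 libraries form 5 groups. At day 4 of culture, 96 hours after the first treatment, there was 1 library each of organoids given the vehicle DMSO, an antagonist of the retinoid X receptors (RXR) at 5 µM, or all-trans retinoic acid at 10 µM, and 1 of organoids kept in vitamin A-free medium. At day 1, after 24 hours, there were 2 libraries of vehicle organoids. RXR proteins are nuclear receptors that bind DNA with partners such as the retinoic acid receptors, PPAR, LXR, FXR and the vitamin D receptor. Retinoic acid is the active form of vitamin A. The labels write both doses with the unit "μm", read here as micromolar.

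The files held 4787 barcodes for the day-4 vehicle, 3570 for the RXR antagonist, 5365 for retinoic acid, 4963 for vitamin A-free medium, and 5576 and 5304 for day-1 libraries 1 and 2. The labels state about 5000 cells per condition. After removal of likely doublets, 4604, 3468, 5135, 4766, 5327 and 5079 cells were kept, in the same order. Their summed unique molecular identifiers (UMIs) were 50040920, 47258161, 60562681, 49237278, 62567817 and 59306794. The median UMIs per cell ranged from 9968 in the vitamin A-free library to 13365.5 in the antagonist library. Cells had been sorted to discard debris and dead cells, so quality values describe sorted cells. The median mitochondrial share was 1.85% in the antagonist library, 4.40% with retinoic acid and 3.58% in the day-4 vehicle. The 10 most abundant genes took 17.1% of UMIs with retinoic acid and from 6.71% to 9.95% in the other 5 libraries. Each treatment had 1 library, so the day-4 comparisons carry no test, and genes are described as higher or lower by size only. Levels are given as CPM, which are UMIs scaled to an equal total in each library, with exact 95% Poisson intervals that cover counting error only.

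The comparison of the RXR antagonist with the vehicle asked what blocking RXR does to organoids at day 4. Genes of absorptive cells were far lower with the antagonist, and genes of regenerating or fetal-like epithelium were far higher. Apoa1, an apolipoprotein of chylomicrons, had 1 UMI with the antagonist against 2490 CPM (2476 to 2504) in the vehicle. This is a ratio of 117662, with a counting interval from 21117 to 4647420. Sis, the brush-border enzyme sucrase-isomaltase, was at 4.17 against 1953 CPM, 468-fold lower (407 to 541). Ly6a, which encodes the surface protein Sca-1, was at 1086 against 2.54 CPM, 428-fold higher (360 to 514), and Ly6d was at 1508 against 0.340 CPM, 4440-fold higher (2773 to 7622).

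Among 8387 genes at 10 CPM or more in at least 1 of these libraries, 580 were at least 2-fold higher with the antagonist and 703 at least 2-fold lower. Of 28 enterocyte genes measured, 26 were at least 1.5-fold lower and 1 was higher, with a median log2 ratio of -3.60. Here and below, list medians are given after subtraction of the median of all genes compared, while members are counted at equal total UMIs. An example besides Apoa1 and Sis was Apoa4, at 3 UMIs against 1012 CPM (ratio 15936, 5453 to 77276). Apoc3 had 0 UMIs and was at least 4293-fold lower, against a floor of 3 UMIs in the library. Metabolic enzymes of enterocytes were also among the 12 lowest genes. The urea-cycle enzymes Cps1 and Otc were 2158-fold and 2728-fold lower, and the carboxylesterase Ces2e was 259-fold lower.

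Of 21 regenerative and fetal-like genes, 20 were at least 1.5-fold higher and 1 was lower, with a median of 3.91. Msln was at 363 CPM against 2 UMIs (ratio 9079, 2513 to 74978), and Anxa3 was 111-fold higher. The calcium-binding S100a6 was at 3082 against 53.4 CPM, and Clu, a marker of revival stem cells, was at 90.7 against 1.32 CPM. Other genes among the 12 highest were the annexins Anxa1 (842-fold), Anxa10 (147-fold) and Anxa5 (49.1-fold), the lectin Lgals3 (58.2-fold) and Sprr1a (105-fold). Tff1, a trefoil peptide typical of gastric mucus cells, was at 182 CPM against 0 UMIs, at least 3031-fold higher. Ly6g was at 305 CPM against 1 UMI (ratio 15246, 2736 to 602219). Of 7 targets of YAP and TEAD measured, 5 were higher and 1 lower (median 1.97), among them F3 at 472 against 13.4 CPM and Ccn2 at 20.9 against 0.580 CPM.

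Secretory lineages moved apart. Of 10 goblet genes, 9 were at least 1.5-fold higher and 0 lower (median 1.21), with the lectin Zg16 at 1368 against 84.1 CPM and the mucin Muc2 at 78.2 against 12.1 CPM. Of 10 Paneth genes, 6 were lower and 2 higher (median -1.17), with the lysozyme Lyz1 at 1.93 against 148 CPM, and Nupr1, a stress-response gene, 19.4-fold higher. Of 9 enteroendocrine genes, 3 were higher and 1 lower (0.39). The glucagon gene Gcg was 8.52-fold and Cck 5.53-fold higher. Tuft genes (3 measured, 1 higher and 1 lower, 0.10) and M-cell genes (5 measured, 2 higher and 1 lower, 0.36) were few.

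Crypt stem-cell and cell-cycle genes were mostly lower with the antagonist. Of 17 stem-cell genes, 11 were lower and 2 higher (median -1.38). Olfm4 was at 0.656 against 279 CPM, and the stem-cell receptor gene Lgr5 was at 12.5 against 36.6 CPM. Of 10 Wnt targets, 4 were lower and 1 higher (-0.48), with Axin2 9.30-fold and Ascl2 14.4-fold lower. Among DNA replication genes, 19 of 20 were lower (-1.21), and among mitosis genes 19 of 22 (-1.05), with 0 higher in either list. Mki67 was at 39.4 against 95.7 CPM. Of 6 Notch pathway genes, 2 were lower and 0 higher (-0.52), with the ligand Dll1 9.70-fold lower.

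Target genes of RXR partners were lower for some receptors and mixed for others. Enterocyte-like cells, named from clusters below, were 1 of 3468 with the antagonist and 29.6% of the vehicle, so no comparison within them could be made. These lists therefore do not separate lower target expression from fewer such cells. Of 17 targets of the vitamin D receptor, PXR and CAR, 11 were lower and 2 higher (median -1.53). Cyp2b10 was 312-fold lower and Cyp3a11 at 0 UMIs, at least 1372-fold lower. Of 11 LXR targets, 7 were lower and 0 higher (-0.74), with the sterol exporters Abcg5 and Abcg8 25.2-fold and 19.8-fold lower. Of 22 PPAR targets and fatty acid oxidation genes, 6 were lower and 5 higher (0.15). Acaa1b was 272-fold lower. Of 5 FXR and bile acid genes, 2 were lower and 2 higher (0.53). The bile acid exporters Slc51a and Slc51b were 187-fold and 177-fold lower, and the importer Slc10a2 was 8.07-fold higher. The unshifted median of this list, 0.54, was -1.51 when each cell had equal weight. Of 14 genes of retinoid metabolism and receptors, 8 were lower and 3 higher (-0.95), with the retinol enzymes Rdh7 107-fold and Adh1 22.3-fold lower. Of 8 retinoic acid response genes, 4 were lower and 3 higher (-0.15), with Dhrs3 2.76-fold lower and Aqp3 83.9-fold higher. The receptor genes were at 9.23 against 19.7 CPM for Rxra, 24.8 against 33.97 CPM for Rxrb and 11.7 against 2.498 CPM for Rarg. Rxrg had 0 UMIs in both libraries.

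Stress and host defence lists were mixed. Of 15 NRF2 targets, which protect against oxidants, 9 were higher and 0 lower (median 0.68), with Slc7a11 17.1-fold and Hmox1 10.5-fold higher. Of 17 glycolysis and hypoxia genes, 7 were higher and 0 lower (0.48), with the glucose transporter Slc2a1 5.05-fold higher. Of 14 p53 targets, 5 were higher and 1 lower (0.35). Of 8 antimicrobial genes, 5 were lower and 3 higher (-2.22). The unshifted median changed to 0.12 without the expression floor. Reg3a was 1159-fold and Reg1 15.6-fold lower. Of 5 antigen presentation genes, 3 were lower and 1 higher (-0.91), and the unshifted median was 0.49 at a floor of 50 CPM. Lists near 0 were interferon response (6 measured, -0.15), unfolded protein response (15, 0.09), cholesterol synthesis (22, 0.01), intestinal transcription factors (14, -0.01), villus tip enterocyte (10, -0.02) and immediate early genes (17, -0.05). The signs of the last 3 unshifted medians changed under TMM scaling or DESeq2 size factors, and those of cholesterol synthesis and immediate early genes when cells had equal weight. Among lists with a median at least 1.5-fold apart, the bootstrap intervals of the stem-cell, Paneth, retinoid metabolism, antigen presentation and antimicrobial lists included 0 before the subtraction. Genes of immune, fibroblast, endothelial and red blood cells had at most 1 measured member in any comparison.

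**Figure D1:**
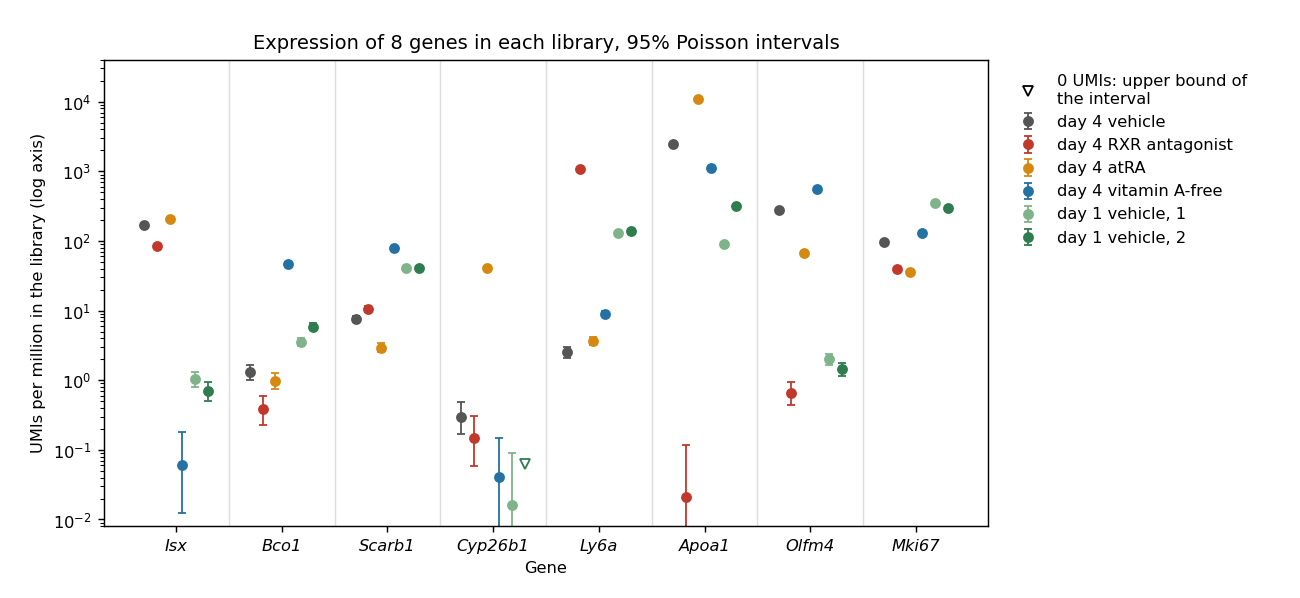
Levels of 8 genes (CPM, log axis) in each of the 6 libraries; points are library sums, bars are exact 95% Poisson intervals, and open triangles mark the upper bound at 0 UMIs. Ly6a was at 1086 CPM with the RXR antagonist, Cyp26b1 at 41.6 CPM with retinoic acid, and Bco1 at 46.0 CPM in vitamin A-free medium.

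The comparison of retinoic acid with the vehicle asked what an excess of the ligand does at day 4. Genes of fatty acid oxidation, bile acid handling and absorption were higher with retinoic acid, and genes of crypt cells, Paneth cells, cell division and glycolysis were lower. Cyp26b1, which encodes an enzyme that degrades retinoic acid, was at 41.6 CPM (39.95 to 43.2) against 0.300 (0.168 to 0.494), 139-fold higher (83.9 to 248). Fabp6, the ileal bile acid-binding protein, was at 250 CPM against 7 UMIs, 1789-fold higher (868 to 4451). Cyp4a10, a fatty acid hydroxylase under PPAR-alpha control, was 1072-fold higher (492 to 2921), and Pdk4, which restrains glucose oxidation, was 130-fold higher (86.7 to 206).

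Among 7976 genes compared, 223 were at least 2-fold higher and 418 at least 2-fold lower at equal total UMIs. The split depended on the scaling, because the median of all genes was -0.27 at equal totals, 0.07 with TMM factors and 0.11 with DESeq2 size factors. The counts were 449 higher and 123 lower with TMM, and 485 higher and 109 lower with DESeq2 factors. Of 25 PPAR and fatty acid oxidation genes, 22 were at least 1.5-fold higher and 0 lower, with a median of 1.75 above that of all genes. Acaa1b was at 712 against 63.3 CPM. Of 6 FXR and bile acid genes, 5 were higher and 0 lower (2.94). Besides Fabp6, the bile acid exporter Slc51b was 8.74-fold higher, and Nr0b2, which encodes the repressor SHP, was 20.7-fold higher. Of 17 targets of the vitamin D receptor, PXR and CAR, 10 were higher and 1 lower (1.39), with Cyp3a11 6.95-fold and S100g, a calcium-binding protein, 3.92-fold higher. Of 11 LXR targets, 5 were higher and 0 lower (0.65), with the desaturase Scd1 at 2629 against 418 CPM.

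Of 29 enterocyte genes, 19 were higher and 0 lower (median 1.15), with Fabp2 7.33-fold and Apoa1 4.45-fold higher. Of 12 genes of retinoid metabolism and receptors, 6 were higher and 0 lower (0.80). Retsat, which saturates retinol, was 6.92-fold higher and the retinol-binding Rbp2 was at 16122 against 6279 CPM. Of 7 retinoic acid response genes, 1 was higher (Cyp26b1) and 2 lower (Nedd9 and Cdx1), with a median of 0.32. Of 13 NRF2 targets, 4 were higher and 1 lower (0.66), with malic enzyme, Me1, 5.84-fold higher. Of 5 antigen presentation genes, 3 were higher and 0 lower (0.89), including H2-K1 at 1352 against 707 CPM. Of 6 antimicrobial genes, 3 were higher and 1 lower (0.70), and of 6 interferon response genes 1 was higher and 1 lower (0.48). Rxra was at 18.3 against 19.7 CPM, Rxrb at 21.2 against 33.97 CPM and Rara at 14.3 against 18.5 CPM.

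Of 17 stem-cell genes, 15 were lower and 1 higher with retinoic acid (median -0.82). Lgr5 was at 5.51 against 36.6 CPM and Olfm4 at 67.6 against 279 CPM. Of 10 Wnt targets, 8 were lower and 0 higher (-0.52), with Myc 3.31-fold lower. All 9 Paneth genes were lower (-0.73), with the defensin Defa24 3.61-fold and Nupr1 14.4-fold lower. All 7 enteroendocrine genes were lower (-1.38), with Cck at 8.34 against 71.7 CPM and the ghrelin gene Ghrl 5.79-fold lower. Among DNA replication genes, 19 of 20 were lower (-0.68), and among mitosis genes 21 of 22 (-0.96). Of 17 glycolysis and hypoxia genes, 15 were lower and 0 higher (-0.75), with the oxygen sensor Egln3 5.28-fold and Slc2a1 4.26-fold lower. Of 22 cholesterol synthesis genes, 17 were lower and 0 higher (-0.51), with Idi1 2.41-fold lower. Immediate early genes (11 of 15 lower, 0 higher, median -1.03) included Atf3 at 17.0 against 85.4 CPM and Fos at 180 against 661 CPM. Unfolded protein response genes (9 of 14 lower, 0 higher, -0.45) included Chac1 6.98-fold lower. Counted relative to the median of all genes, a count chosen after the data were seen, lower members were 7 of 22 for cholesterol synthesis, 4 of 10 for Wnt, 5 of 14 for unfolded protein response, 2 of 5 for Notch, 9 of 17 for glycolysis, 13 of 20 for DNA replication and 21 of 22 for mitosis. Higher members by this count were 28 of 29 for enterocyte, 7 of 13 for NRF2 (0 lower) and 3 of 6 for interferon genes (1 lower). Smaller lists were Notch (4 of 5 lower, -0.46), YAP and TEAD (2 of 3 lower, -0.70) and M cell (3 of 5 lower, -0.66). Goblet (8 measured, -0.21), villus tip (9, -0.10), intestinal transcription factors (14, -0.10), regenerative genes (8, 0.06) and p53 targets (10, -0.10) lay near 0. The unshifted medians of the last 2 changed sign with DESeq2 factors. The intervals of the retinoid metabolism, antimicrobial and M-cell medians included 0. Only 2 tuft genes were measured here and in vitamin A-free medium. The lowest gene was Ctrb1, a chymotrypsinogen gene, at 9.38 against 688 CPM.

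Within clusters of the same name, 472 stem-like cells of the retinoic acid library were set against 1277 of the vehicle. Of 20 PPAR and fatty acid oxidation genes, 11 were higher and 1 lower (unshifted median 0.62), and 16 of 17 glycolysis genes were lower (-1.17). The enterocyte list was at -0.08 there. The lower levels of stem-cell and cell-cycle genes over all cells were not seen within this class. The stem-cell list was at -0.04, with 2 of 18 members higher and 1 lower, mitosis genes at -0.01 and DNA replication genes at 0.20, with 0 of 22 members 1.5-fold apart in both. The class was named from markers that are also on the stem-cell list, and clustering groups cells alike in such genes. These medians were therefore partly set by how the class was made, and no conclusion is drawn from them. Cyp26b1 was at 15.7 against 0.136 CPM. Lyz1 was at 185 against 37.2 CPM, while the Paneth list was at -0.49 (-0.56 to 0.81 over the 6 other settings). In 4502 against 1363 enterocyte-like cells, 20 of 25 PPAR genes were higher (1.24), as were 7 of 28 enterocyte genes (0.26, 1 lower), and 18 of 22 cholesterol synthesis genes were lower (-0.74). Of the 1363 vehicle cells, 1362 sat in a cluster with 8 retinoic acid cells, so the class compares different clusters. The genes 2-fold apart in this class were 115 higher and 173 lower, and over the 6 other settings 131 to 190 higher and 229 to 435 lower.

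The comparison of vitamin A-free medium with the vehicle asked what the absence of the vitamin does. Whether the vitamin A-free organoids were given DMSO is not stated. Differences were few, and those of Isx, Bco1 and Scarb1 were among the largest. Isx, an intestinal homeobox repressor induced by retinoic acid, had 3 UMIs against 172 CPM (168 to 176), a ratio of 2823 (966 to 13693). Bco1, the enzyme that cleaves beta-carotene to retinal, was at 46.0 against 1.30 CPM, 35.4-fold higher (27.7 to 46.0). Scarb1, a lipid and carotenoid receptor, was at 80.0 against 7.49 CPM, 10.7-fold higher (9.60 to 11.9). In clusters of enterocyte-like cells alone, Isx was at 0 UMIs against 169.5 CPM, Bco1 at 131 against 0.848 CPM and Scarb1 at 145 against 3.63 CPM. In stem-like cells alone, Isx was at 0 against 148 CPM and Scarb1 at 35.8 against 14.8 CPM. Across the other libraries, Scarb1 was at 10.6 CPM with the antagonist, 2.92 with retinoic acid, and 40.8 and 40.6 at day 1.

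Among 8180 genes compared, 15 were at least 2-fold higher and 16 at least 2-fold lower in vitamin A-free medium, or 10 higher and 31 lower with TMM scaling. The median of all genes was 0.08 at equal totals and -0.04 with TMM. For scale, the 2 day-1 libraries, which share a condition, were at least 2-fold apart in 65 of 8207 genes. Library 2 over 1 had medians, after the same subtraction, of 0.68 for enterocyte, 1.22 for Paneth and -0.36 for stem-cell genes. List shifts of the size given next therefore do not by themselves tell the medium from a difference between libraries. Of 17 stem-cell genes, 10 were at least 1.5-fold higher and 0 lower, with a median of 0.59. Lgr5 was at 74.8 against 36.6 CPM and Olfm4 at 552 against 279 CPM. Of 11 Wnt targets, 5 were higher and 0 lower (0.35), with Axin2 1.95-fold higher. Of 10 Paneth genes, 8 were higher and 0 lower (0.62), with Ang4, an antimicrobial angiogenin, 3.46-fold and Itln1 1.99-fold higher. Of 28 enterocyte genes, 12 were lower and 0 higher (-0.63), with Apoa1 2.19-fold and the peptidase Anpep 2.05-fold lower. Goblet genes were split, with 3 of 10 higher and 1 lower (0.40), and Clca1 3.25-fold lower. Counts relative to the median of all genes were chosen after the data were seen. By these, 9 of 17 stem-cell, 4 of 11 Wnt, 5 of 10 Paneth and 1 of 10 goblet genes were higher. Lower by them were 18 of 28 enterocyte genes and 1 goblet gene. Other named genes included the flavin enzyme Fmo5 (5.69-fold lower), the cytokine Il18 (3.18-fold lower), Lypd8 (1526 against 3537 CPM) and Tubb2b (5.39-fold higher).

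In vitamin A-free medium, of 7 retinoic acid response genes, 2 were lower (Isx and Dhrs3) and 1 higher (Lrat), with a median of -0.23. Of 13 genes of retinoid metabolism and receptors, 2 were higher (Bco1 and Scarb1) and 1 lower (-0.17). Both DNA replication genes (21 measured, 0.32) and mitosis genes (22, 0.30) lay above all 10000 random lists of like expression, as a description of these libraries, with 0 members 1.5-fold apart. Between the 2 day-1 libraries, DNA replication genes (-0.34, library 2 over 1) likewise lay below all 10000 random lists. Such a place thus also arose without a treatment. Within stem-like cells of the vitamin A-free library against the vehicle, the unshifted medians had the opposite sign. They were -0.08 for DNA replication (-0.09 to 0.16 over the 6 other settings) and -0.13 for mitosis (-0.65 to -0.10). FXR genes (2 of 3 lower, -0.77) included the bile acid exporter Slc51a 3.62-fold lower. At equal totals no member was 1.5-fold apart among LXR (11 measured, -0.17), vitamin D receptor, PXR and CAR (17, -0.31), cholesterol (22, -0.19), Notch (5, 0.16), p53 (12, -0.06), unfolded protein (15, -0.06), glycolysis (17, -0.07), immediate early (15, 0.00) or villus tip genes (9, 0.00). Medians of the other lists were 0.25 for enteroendocrine (8 measured), 0.17 for M cell (6), 0.16 for regenerative (8) and 0.34 for YAP and TEAD genes (4). They were -0.18 for PPAR (22), -0.12 for intestinal transcription factors (14), 0.00 for interferon response (4), -0.34 for antigen presentation (5), -0.38 for antimicrobial (6) and -0.36 for NRF2 genes (13). The unshifted medians of villus tip, interferon, p53, unfolded protein, glycolysis and immediate early genes changed sign with TMM scaling. The receptor genes differed little, with Rxra at 18.6 against 19.7 CPM and Rara at 19.2 against 18.5 CPM.

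The antagonist and retinoic acid libraries were also set against each other. Enterocyte genes were lower with the antagonist in 26 of 28 measured and higher in 0 (median -4.94). Regenerative genes were higher in 19 of 21 and lower in 0 (3.96). Apoa1 had 1 UMI against 11090 CPM, Cyp3a11 had 0 UMIs and was at least 9530-fold lower, and Acaa1b was 3059-fold lower. Nupr1 was 278-fold higher and F3 108-fold higher with the antagonist. Among 8191 genes, 1087 were at least 2-fold higher and 747 lower, or 733 higher and 1065 lower with TMM scaling, which moved the median of all genes from 0.33 to 0.04.

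Targets of several RXR partners were mostly lower with the antagonist than with retinoic acid, while of 9 retinoic acid response genes 4 were higher and 4 lower. Enterocyte-like cells were 1 of 3468 with the antagonist and 87.7% with retinoic acid, so these lists do not separate lower target expression from fewer such cells. Lower were 21 of 25 PPAR genes (median -1.64), 8 of 11 LXR targets (-1.78), 5 of 8 FXR genes (-3.19) and 13 of 17 targets of the vitamin D receptor, PXR and CAR (-2.16). Higher members numbered 0, 0, 1 and 1. Fabp2 was 37.7-fold lower, Abcg5 48.7-fold lower and Fabp6 986-fold lower. Retinoid metabolism and receptor genes were lower in 8 and higher in 3 of 14 (-1.19). Higher with the antagonist were goblet genes (9 of 10, 1.38), enteroendocrine genes (8 of 9, 1.496), glycolysis genes (16 of 17, 1.00) and immediate early genes (12 of 17, 0.97). The same held for YAP and TEAD targets (6 of 7, 1.99). Unfolded protein response genes (12 of 15, 0.45), cholesterol synthesis genes (15 of 22, 0.43) and p53 targets (8 of 14, 0.36) were higher at equal totals, but relative to the median of all genes these counts were 5, 7 and 3. Egln3 was 13.7-fold, Chac1 23.7-fold and Cck 47.6-fold higher. Antimicrobial genes were lower in 5 and higher in 3 of 8 (-3.29), with an unshifted median of 0.10 without the floor. DNA replication genes lay at -0.64 (16 measured) and mitosis genes at -0.08 (21), and the sign of the latter's unshifted median, 0.25, changed under TMM scaling. Medians of the other lists were -0.11 for retinoic acid response (9 measured), -0.40 for stem cell (15), 0.49 for Wnt (7), 0.97 for villus tip (9) and -0.02 for intestinal transcription factors (14). They were 0.20 for Paneth (8), 1.30 for tuft (3), 0.97 for M cell (5), 0.37 for Notch (3), -0.61 for interferon (6), -1.37 for antigen presentation (5) and 0.14 for NRF2 genes (15). Among lists with a median at least 1.5-fold apart, the intervals of the FXR (-6.07 to 0.23), retinoid metabolism (-4.51 to 0.26), antimicrobial (-3.94 to 2.05), villus tip, tuft, interferon and antigen presentation lists included 0 before the subtraction. With TMM or DESeq2 scaling the signs of the unshifted medians of retinoic acid response, transcription factor and Notch genes changed.

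**Figure D2:**
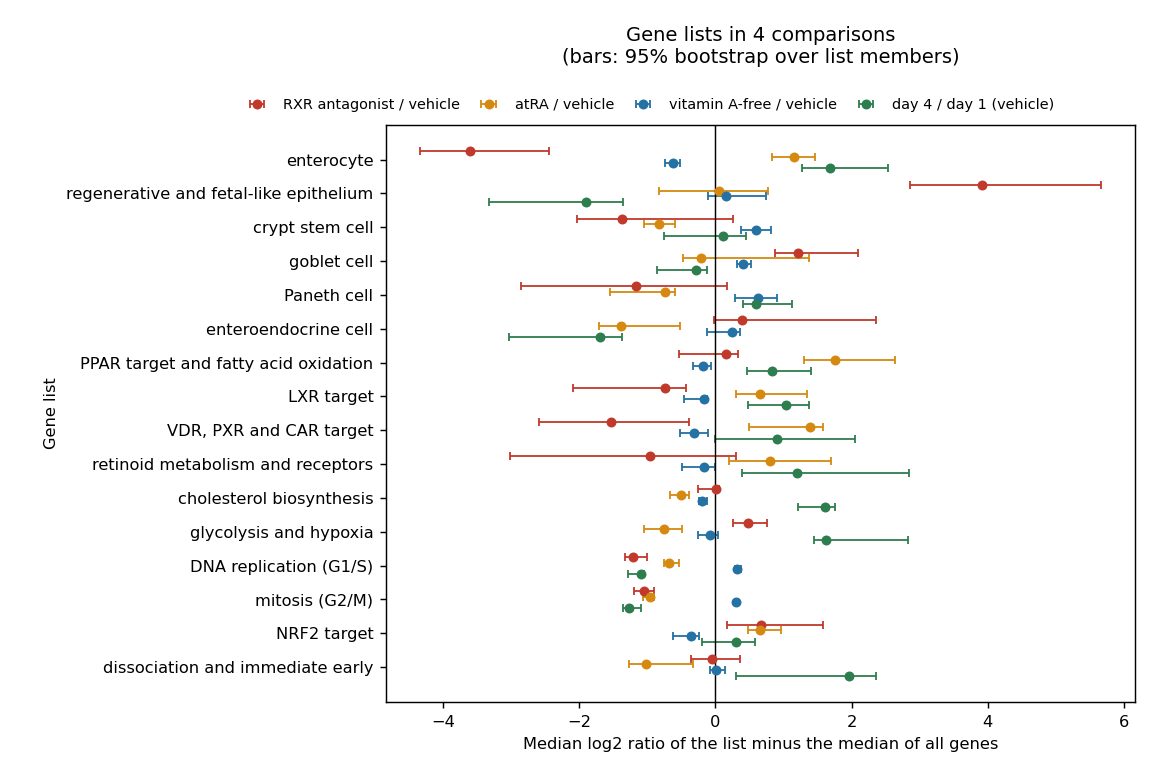
Median log2 ratios of 16 gene lists, minus the median of all genes, in 4 comparisons; bars are 95% bootstrap intervals over list members. The enterocyte list was at -3.60 for the RXR antagonist and 1.15 for retinoic acid, and the regenerative list was at 3.91 for the antagonist.

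The comparison of the day-4 with the day-1 vehicle described the course of organoid growth from single cells. Isx rose from 1.04 and 0.691 CPM in the day-1 libraries to 172 CPM, a log2 change of 7.81 (SE 0.24, adjusted p = 0.000355, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Olfm4 rose from 2.01 and 1.45 to 279 CPM (7.51, SE 0.23, adjusted p = 0.000355, edgeR). Regenerative genes fell. Ly6a was at 130.5 and 137 CPM at day 1 and 2.54 CPM at day 4, a log2 change of -5.54 (SE 0.21, adjusted p = 0.000374, edgeR). Gcg fell from 164 and 546 to 6.65 CPM (-5.55, SE 0.85, adjusted p = 0.00606, edgeR).

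Of 17592 genes tested with edgeR, 3044 rose and 2975 fell at an adjusted p of 0.05. This p measures the spread between the 2 day-1 libraries alone, with 1 residual degree of freedom, and the lone day-4 library is assumed to vary like them. That spread may be technical, since the labels do not say that the day-1 libraries were separate cultures, only that organoids came from 2 mice in duplicate. In simulated data, false calls were a larger share of all edgeR calls than the 0.05 aimed at. Day was also tied to medium. Until day 3 the medium held 20% Wnt3a-conditioned medium, 10 µM of the ROCK inhibitor Y-27632 and 3 µM of CHIR99021, an activator of Wnt signalling, and treatment was repeated at the change.

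Absorptive genes rose. Of 30 enterocyte genes, 25 rose, 0 fell and 5 did not pass, or 27, 0 and 3 when adjusted over the list alone. Apoa1 rose from 91.9 and 323 to 2490 CPM, and Apoa4 from 41.2 and 115 to 1012 CPM. Of 17 genes of retinoid metabolism and receptors, 10 rose, 5 fell and 2 did not pass (12, 5 and 0 adjusted over the list alone). Adh1 rose from 6.60 and 17.7 to 588 CPM and Rdh7 from 5.98 and 13.0 to 207 CPM. Of 10 retinoic acid response genes, 6 rose, 2 fell and 2 did not pass, with the same counts when adjusted over the list alone. Dhrs3 rose from 6.94 and 10.7 to 79.8 CPM. Antimicrobial genes rose in 4, fell in 1 and did not pass in 8 of 13 (5, 1 and 7 over the list alone), with Reg1 at 8.81 and 17.3 CPM at day 1 and 624 CPM at day 4. Among intestinal transcription factors, 8 of 16 rose and 0 fell (9 over the list alone), and among villus tip genes 6 of 12 rose and 0 fell (7 over the list alone).

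Regenerative genes fell in 17, rose in 1 and did not pass in 6 of 24 tested, also when adjusted over the list alone. Msln was at 71.0 and 124 CPM at day 1 and at 2 UMIs at day 4, a ratio of 2443 (671 to 20031). S100a6 fell from 959 and 1018 to 53.4 CPM. YAP and TEAD targets fell in 8, rose in 2 and did not pass in 10 of 20, with the same counts over the list alone. F3 fell from 47.8 and 71.8 to 13.4 CPM, and Ccn1 rose from 10.5 and 14.2 to 24.2 CPM. All 22 mitosis genes and 21 of 22 DNA replication genes fell (22 of 22 over the list alone). Mki67 fell from 353 and 299 to 95.7 CPM. Of 20 enteroendocrine genes, 8 fell, 0 rose and 12 did not pass, likewise over the list alone. Cck fell from 536 and 1821 to 71.7 CPM (log2 -3.86, SE 0.77, adjusted p = 0.0136, edgeR).

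Of 22 cholesterol synthesis genes, 21 rose, 0 fell and 1 did not pass, with the same counts over the list alone, and Insig1 rose from 90.3 and 79.1 to 500.2 CPM. Of 17 glycolysis and hypoxia genes, 16 rose and 0 fell, likewise over the list alone, with Ankrd37 at 9.70 and 12.3 CPM at day 1 and 167 CPM at day 4. Immediate early genes rose in 10, fell in 3 and did not pass in 5 of 18, likewise over the list alone. Jun rose from 65.4 and 98.2 to 511 CPM. PPAR and fatty acid oxidation genes rose in 15, fell in 3 and did not pass in 7 of 25 (17, 3 and 5 over the list alone). Acaa1b rose from 3.60 and 6.81 to 63.3 CPM. LXR targets rose in 9 of 15 and fell in 0 (10 over the list alone), FXR genes rose in 4 and fell in 2 of 8, and targets of the vitamin D receptor, PXR and CAR rose in 10 and fell in 2 of 18 (11 and 2 over the list alone). Stem-cell genes rose in 5, fell in 5 and did not pass in 10 of 20, and Wnt targets rose in 1, fell in 7 and did not pass in 11 of 19. Lgr5 rose from 10.5 and 6.17 to 36.6 CPM, while Cd44 fell from 49.9 and 41.9 to 12.9 CPM and Ccnd1 from 129 and 109 to 32.1 CPM.

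Paneth genes rose in 7 and fell in 0 of 17 from day 1 to day 4. Goblet genes rose in 1 and fell in 0 of 16 (0 and 0 over the list alone), and tuft genes rose in 3 and fell in 0 of 11 (5 over the list alone). M-cell genes rose in 2 and fell in 1 of 7, and Notch genes rose in 4 and fell in 1 of 12. Interferon genes rose in 6 and fell in 2 of 17 (7 and 2 over the list alone), and antigen presentation genes rose in 4 and fell in 2 of 12. Numbers that rose and fell were 5 and 6 of 16 for p53 targets, 4 and 1 of 15 for NRF2 targets, and 5 and 2 of 15 for unfolded protein response genes (6 and 2 over the list alone). For FXR, stem-cell, Wnt, Paneth, M-cell, Notch, antigen presentation, p53 and NRF2 lists, the counts over the list alone equalled those over all genes. Of immune, fibroblast and endothelial genes, 2, 3 and 2 could be tested, of which 1, 1 and 0 rose and 0 fell. By size, 655 of 8524 genes were at least 2-fold higher and 899 lower at day 4, or 819 and 587 with TMM scaling, which moved the median of all genes from -0.18 to -0.02. With the DESeq2 test 2403 genes rose and 2626 fell.

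Clusters of all cells were named from marker genes fixed before the data were examined. Intervals of shares are exact binomial (Clopper-Pearson) and cover counting error only. The shares depended on the clustering, so the gene levels above carry the comparisons. Enterocyte-like cells made up 29.6% (28.3 to 30.9) of the day-4 vehicle, 87.7% (86.7 to 88.6) with retinoic acid and 23.6% (22.4 to 24.9) in vitamin A-free medium, and 1 of 3468 cells with the antagonist. A further 37.7% of the vehicle and 27.5% of the vitamin A-free library were in unnamed clusters. At a lower resolution the enterocyte-like share was 67.7% in the vehicle and 51.5% in vitamin A-free medium. Stem-like cells were 27.7% (26.4 to 29.1) of the vehicle, 9.19% (8.42 to 10.02) with retinoic acid, 41.9% (40.5 to 43.3) in vitamin A-free medium and 0.577% with the antagonist. Regenerative-like cells were 53.8% (52.2 to 55.5) of the antagonist library, 0.0652% of the vehicle, and 0.0188% and 0 at day 1, where 0 of 5079 cells allows up to 0.0591% by a limit of 3 counts. The antagonist share was 94.7% at resolution 0.5 and 94.8% with the stricter cell filter. The day-1 shares were 9.57% and 15.1% at resolution 2, and 11.5% in library 2 clustered alone, so a low share at day 1 depended on the clustering. Cells in clusters of cycling markers made up 74.3% and 54.3% of the day-1 libraries. This is not a share of all cycling cells, since a stem-like cluster of day 4 also had cell-division genes among its top genes, and the antagonist library had 6 cells in it. Goblet- and Paneth-like cells ranged from 1.85% with retinoic acid to 4.57% in vitamin A-free medium at day 4, and were 3.49% and 5.91% at day 1. At resolution 2 the day-4 shares ran from 0.954% with retinoic acid to 3.52% with the antagonist. Enteroendocrine-like cells were 1.43% of the vehicle, 0.980% with the antagonist, 0.779% with retinoic acid, 1.91% in vitamin A-free medium, and 2.97% and 7.91% at day 1. With a stricter cell filter the day-1 shares were 0.869% and 5.49%, and with each library alone the share with retinoic acid was 0. There were 17 tuft-like cells in all, but 0.173% to 2.43% of each library at resolution 2 and 0 at resolution 0.5, and no cluster met the M-cell markers.

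Unnamed clusters also held 40.9% of the antagonist library and 19.0% and 31.7% of the day-1 libraries, and 0.331% with retinoic acid. Over the other settings these shares ran from 0.0577% to 45.6% with the antagonist and from 0.156% to 13.6% with retinoic acid. At day 1 they ran from 14.1% to 41.3% and from 14.5% to 45.4%. The threshold for a name was set after the data were seen. Most clusters came from 1 treatment or day, so a cluster may be that library and not a cell type.

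**Figure D3:**
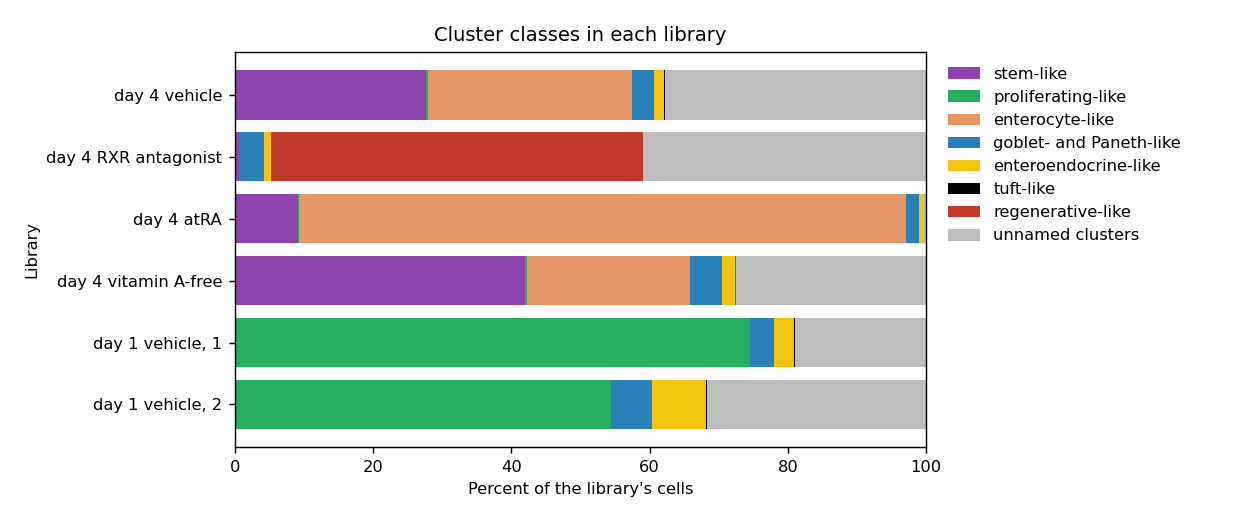
Percent of each library's cells in each cluster class, as stacked bars for the 6 libraries. Enterocyte-like cells made up 29.6% of the day-4 vehicle and 1 of 3468 cells with the RXR antagonist, where 53.8% were regenerative-like and 40.9% were in unnamed clusters. At resolution 0.5 the regenerative-like and unnamed shares with the antagonist were 94.7% and 0.0577%.

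After each cell was thinned to 3000 UMIs, Ly6a was seen in 57.5% (55.8 to 59.2) of antagonist cells, and in 72.2% without thinning. It was seen in 0.471% of vehicle cells (1.06% unthinned), and in 21.8% and 20.1% at day 1 (41.6% and 36.6% unthinned). Free RNA gives UMIs in cells that do not express a gene, so shares in enteroendocrine-like cells are given for comparison. For Ly6a these were 18.8% with the antagonist, 9.52% in the vehicle, and 10.3% and 12.7% at day 1. In the vehicle this share was above that of all cells, so it did not measure free RNA alone, and no share is read as background from it. Apoa1 was seen in 0 of 3380 antagonist cells (by the same limit up to 0.0888% of cells with a UMI at this depth, 0.0288% unthinned), and in 55.8% of vehicle cells (65.2% unthinned) against 9.52% of enteroendocrine-like cells. Olfm4 was seen in 13.8% of vehicle cells (17.9% unthinned, 6.35% of enteroendocrine-like cells), 22.5% in vitamin A-free medium (28.4%, enteroendocrine-like 9.76%) and 0.207% with the antagonist (0.433%, enteroendocrine-like 3.12%). Lgr5 was seen in 8.64% of vehicle cells (18.1% unthinned, enteroendocrine-like 3.17%), 16.9% in vitamin A-free medium (32.6%, enteroendocrine-like 7.32%) and 1.58% with retinoic acid (3.56%, enteroendocrine-like 8.11%). With the antagonist Lgr5 was seen in 3.82% of cells (12.6% unthinned, enteroendocrine-like 3.12%). Cyp26b1 was seen in 7.87% of retinoic acid cells (17.6% unthinned, enteroendocrine-like 0 of 37) and in 0.0898% of vehicle cells (0.217%, enteroendocrine-like 0 of 63). Mki67 was seen in 14.8% of vehicle cells (25.2% unthinned, enteroendocrine-like 3.17%), 6.54% with the antagonist (14.6%, enteroendocrine-like 0 of 32), and 56.1% and 45.0% at day 1 (80.9% and 66.0%, enteroendocrine-like 5.17% and 2.91%). Median depths before thinning in the enteroendocrine-like cells were 5675 UMIs in the vehicle, 7121.5 with the antagonist, 5593 with retinoic acid, 5505 in vitamin A-free medium, and 3736.5 and 4197 at day 1.

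Gene models follow the GENCODE M21 annotation of the GRCm38 genome. Isx (ENSMUSG00000031621.9) lies on chromosome 8 from 74873173 to 74893506, and Bco1 (ENSMUSG00000031845.15) on the same chromosome from 117095854 to 117133720. Scarb1 (ENSMUSG00000037936.15) lies on chromosome 5 from 125277087 to 125341094, and Cyp26b1 (ENSMUSG00000063415.12) on chromosome 6 from 84571414 to 84593908. Ly6a (ENSMUSG00000075602.10) and Ly6d (ENSMUSG00000034634.7) lie on chromosome 15, from 74994877 to 74998031 and from 74762056 to 74763620. Apoa1 (ENSMUSG00000032083.8) lies on chromosome 9 from 46228580 to 46230466, and Sis (ENSMUSG00000027790.14) on chromosome 3 from 72888557 to 72967863. Fabp6 (ENSMUSG00000020405.4) lies on chromosome 11 from 43596049 to 43601540, and Cyp4a10 (ENSMUSG00000066072.13) on chromosome 4 from 115518264 to 115533649. Olfm4 (ENSMUSG00000022026.7) lies on chromosome 14 from 79984081 to 80023139, and Gcg (ENSMUSG00000000394.15) on chromosome 2 from 62474530 to 62483650.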

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

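Every alternative was planned before the data were examined, except the counts of list members relative to the median of all genes, which were chosen after the data were seen. Of 294 such counts, 250 were within 1.5 times the count at equal totals, 24 were lower and 20 higher. Of 5117 values of named genes at least 2-fold apart, under all alternatives, 0 changed sign. Pseudocounts and floors cannot change the sign of a gene's ratio. TMM and DESeq2 factors moved all genes by too little to do so for genes 2-fold apart, such as a median from -0.27 to 0.11 with retinoic acid. Only the alternatives in the choice, weight or thinning of cells and in the day-1 libraries could have done so. Of 849 values of the 75 list medians at least 1.5-fold apart, 4 changed sign. Of 72 list medians under 1.5-fold, 30 changed sign under at least 1 alternative. Of 1649 list medians under an alternative, 1524 moved by less than their spread. Keeping all deposited barcodes equalled keeping doublets, because the filter removed 0 barcodes. List medians in this part are not shifted by the median of all genes.

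For the antagonist against the vehicle, the antimicrobial list was at 0.12 without a floor (-2.21 in the main setting), since the floor's removal brings in members near 0 UMIs. The antigen presentation list was at 0.49 with a floor of 50 CPM (-0.90 in the main setting), which leaves fewer members. The enterocyte list was at -4.56 with a pseudocount of 1 CPM. With a floor of 50 CPM, 312 genes were higher and 370 lower, since fewer genes are compared.

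For retinoic acid against the vehicle, TMM scaling gave 449 genes higher and 123 lower, and list medians of 0.51 for retinoic acid response, -0.79 for stem cell, 1.23 for enterocyte and -0.90 for mitosis. DESeq2 size factors gave 485 and 109, with 0.55, -0.75, 1.28 and -0.86. These scalings shift all genes of the pair by 1 factor. The mitosis list was at -1.13 with equal cell weight, -1.13 in thinned cells, -1.41 and -1.10 with pseudocounts of 1 and 10 CPM, against -1.23 in the main setting. Lower genes numbered 725 with a pseudocount of 1, 251 with 10, and 226 with a floor of 50 CPM, where the stem-cell list was at -1.44. In the enterocyte-like class with the stricter cell filter, the goblet list was at -0.51 (0.65 in the main setting). The cause was not tested.

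For vitamin A-free medium, lower genes numbered 31 with TMM and 32 with DESeq2 factors. The enterocyte list was at -0.67 and -0.69 with them, the mitosis list at 0.24 and 0.23, and the PPAR list at -0.25 with DESeq2 factors. The mitosis list was at 0.33 with equal cell weight, 0.36 in thinned cells, 0.41 with a pseudocount of 1 and 0.35 with 10, against 0.38 in the main setting. With a pseudocount of 1, 26 genes were higher and 25 lower. With 10, 10 were lower, and with a floor of 50 CPM 8 were higher.

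For the antagonist against retinoic acid, the mitosis list was at -0.044 with TMM, -0.077 with DESeq2 factors and 0.42 with a floor of 50 CPM, against 0.25. The Notch list was at -0.022 with DESeq2 factors and the antimicrobial list at 0.10 without a floor, both reversed. DESeq2 factors left 706 genes higher. A pseudocount of 1 gave -5.50 for the enterocyte and 5.32 for the regenerative list. With a floor of 50 CPM, 592 genes were higher and 450 lower.

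For day 4 against day 1, TMM gave 587 genes lower and a mitosis median of -1.27. That median was -1.55 with equal cell weight and -1.57 in thinned cells. The regenerative list was at -1.05 without a floor. With a floor of 50 CPM, 435 genes were higher and 589 lower. Without 1 day-1 library, 562 to 751 genes were higher and 769 to 1049 lower. In edgeR without a count filter 1839 genes fell, of 28578 tested. DESeq2 and edgeR shared 4849 calls, of 5029 and 6019, and 4849 of these had the same direction.

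Of 288 class shares under an alternative, 138 moved, and the cause was not tested. Settings are listed as resolution 0.5, resolution 2, another seed, each library alone, doublets kept and stricter filter. The vehicle stem-like share (27.7%) was 26.2%, 22.1%, 26.0% and 23.7% in the last 4, and the vitamin A-free one (41.9%) was 39.8%, 28.0%, 39.4% and 34.9%. The antagonist's was 0% with each library alone, and its enterocyte-like share was 0% in the last 4 settings. Day-1 shares of cycling clusters were 76.6%, 67.4%, 67.1%, 49.7%, 62.2% and 76.7% in library 1, and 56.9%, 50.2%, 46.5%, 44.5%, 39.8% and 57.8% in library 2. Enterocyte-like shares of the vehicle were 67.7%, 41.4%, 39.2%, 26.97% and 59.7% without the entry for another seed. With vitamin A-free medium they were 51.5%, 32.1%, 27.2% and 44.2% without those for another seed and doublets kept. With retinoic acid they were 84.2%, 77.3%, 74.4%, 78.8% and 77.3% in the last 5. The regenerative-like share of the antagonist library was 94.7%, 55.6%, 64.6%, 48.7% and 94.8% without the entry for another seed.

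Of 144 shares of cells with a UMI under another depth, 104 moved, since depth sets how often a gene is seen. Depth limits genes with few UMIs, and at the lowest total, 47258161 UMIs, 3 UMIs correspond to 0.0635 CPM.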

Other observations

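Tests chosen only after the results were seen were those of cell cycle, enterocyte and regenerative genes against day 1, of enterocyte-like shares in the retinoic acid and vitamin A-free libraries, and of free RNA, which replaced an earlier test that moved nothing. The 2 day-1 libraries differed in secretory genes. Of 8207 genes compared, 65 were at least 2-fold higher in library 2 and 0 in library 1. Of the 65, 12 were on the enteroendocrine list and 14 on the goblet or Paneth list. All 17 enteroendocrine genes measured were at least 1.5-fold higher in library 2 (median log2 ratio 1.40), as were 8 of 9 goblet genes (1.56) and 9 of 9 Paneth genes (1.20). Gcg, the glucagon gene, was at 164 and 546 CPM. Enterocyte genes were higher in 15 of 25 (0.66) and stem-cell genes in 0 of 16 (-0.38). DNA replication genes were at -0.36. The labels name no difference between these libraries.

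The retinoid receptor genes were low in all libraries. Rxra ranged from 9.23 CPM with the antagonist to 19.7 CPM in the day-4 vehicle, and Rara from 14.3 CPM with retinoic acid to 19.2 CPM. Rarb had at most 1 UMI in a library. Cyp26b1 was at 41.6 CPM with retinoic acid and at most 0.300 CPM in the other 5 libraries. Malat1, a nuclear RNA, was at 11521 CPM with the antagonist and at 4389 CPM in the vehicle, and was named after its values were seen, but the test of cells low in it was written before its result.

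In the antagonist library, enterocyte genes were lower and regenerative genes higher than in the vehicle. For a day-1 library under a wrong label, the SD of log2 ratios to the day-1 mean was 0.968, or 4.23 times the 0.229 between the day-1 libraries, but a spread from 1 pair does not decide. Leaky cells rich in nuclear RNA are argued against, since 434 antagonist cells with no more Malat1 than the vehicle median had an enterocyte median of -4.05 (-4.75 to -3.09) and a regenerative median of 4.12 (2.72 to 5.05). That label error and expression kept from day 1 are argued against by medians against the day-1 mean. These were -1.95 (-3.38 to -1.03) for enterocyte and 1.84 (1.64 to 2.56) for regenerative genes. The median of -2.40 (-2.57 to -2.33) for mitosis genes also argues against the label error. It does not decide on expression kept from day 1, since the medium changed at day 3 and all 22 mitosis genes fell in the vehicle too. Over all genes, expression kept from day 1 stays open as a part. The antagonist over the vehicle and day 1 over vitamin A-free day 4 gave r = 0.397 (rho = 0.209) over 8965 genes, which are not independent replicates. Over genes under 2-fold apart between antagonist and vehicle, r was 0.0617. That cut limits 1 of the 2 ratios and by itself lowers r, so no conclusion is drawn from it. A mislabelled sample from outside and an effect of the antagonist also stay open with 1 library.

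In the retinoic acid library, PPAR target and fatty acid oxidation genes were higher. A larger share of enterocyte-like cells as the whole cause is argued against, since the PPAR median was 0.62 (0.38 to 0.99) within stem-like cells, with 11 of 20 genes higher, and 0.55 to 0.82 under 6 other clusterings. For free RNA of enterocyte-like cells in the stem-like droplets, the enterocyte median there was -0.082 (-0.49 to 0.10). This does not decide, because clusters were named from markers on that list. Of its 19 genes measured, 4 were lower and 2 higher, Fabp1 (6982 against 1039 CPM) and Apoa1 (70.1 against 22.8 CPM). A limit came from 14 enterocyte genes at 500 CPM or more in the library. They allow at most 0.632% of library-wide RNA in stem-like cells, which argues against a large part of free RNA but not a small one. A direct effect of retinoic acid through RXR partners, or faster maturation, may explain the pattern, and neither was tested. Differences between single libraries stay open.

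In the vitamin A-free library, Isx was near 0 UMIs, and Bco1 and Scarb1 were higher. A smaller share of enterocyte-like cells is argued against, since within that class Bco1 was 155-fold (91.9 to 283) and Scarb1 39.98-fold higher (30.9 to 52.6), and Isx at least 701-fold lower. In stem-like cells (1998 against 1277), Isx was likewise at 0 against 148 CPM, but Scarb1 was only 2.41-fold higher (35.8 against 14.8 CPM). Bco1 was not among the genes with the highest ratios there. A candidate explanation is that Isx holds Bco1 and Scarb1 down and needs vitamin A. Loss of Isx alone leaves the smaller Scarb1 rise in stem-like cells unexplained. Cell by cell the candidate explanation stayed open. Among vehicle enterocyte-like cells at equal depth, 0.379% (2 of 528, 0.0459 to 1.36) of those with an Isx UMI had a Scarb1 UMI. Of those without, 1.35% (11 of 815, 0.676 to 2.40) had a Scarb1 UMI. The intervals overlap, and a mislabelled library from outside stays open too.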
